A study of Tribolium castaneum with 8 samples.

How the data were processed

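Single-cell RNA libraries were prepared with the 10x Genomics droplet method from embryos of the red flour beetle Tribolium castaneum aged 35 to 50 hours. Per the labels' protocols, embryos were homogenised, the suspension was passed through a 20 μm strainer, and live cells that excluded the dye DAPI were sorted for fluorescence. The sorted cells came from a Gal4 enhancer trap line that drives turbo GFP, a green fluorescent protein, in neuroblasts, the stem cells of the insect nervous system. The labels list 8 libraries in 1 group, with replicate numbers 1 to 8, the same age range and no treatment. The series' design text speaks of 1 line, while the labels give each library its own strain number in an unbroken run. Such a run can arise when a table is filled in, so the strain number was not used as a difference between libraries. Nothing in the labels says that the libraries came from separate embryo collections, so spreads and p-values over libraries measure only the differences between these 8 samples, which may be technical.

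The analysis rests on 1 deposited table with a barcode, a cell label and a species for each of 31573 cells. The table holds no read counts, no expression values and no confidence per cell, so no gene was tested here. Cell Ranger and Scanpy are named in the submitters' processing notes without a version or a role. The name the authors gave the deposited table places its cells among brain neuroblasts and describes the labels as coming from label transfer with Drosophila and Tribolium. Whether the table holds all sorted cells or a part of them was not stated. The method of transfer, its direction, the genome builds, the filters on cells and the treatment of doublets were not given in the sources used here. The table holds 10 labels, and none of its cells has an unassigned, unknown or numeric label (0 cells). Labels are printed as deposited, question marks included. The number of molecules read per cell was not used here, so differences in sequencing depth between libraries could not be examined.

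Each barcode has 16 bases. Every Tribolium barcode carries a suffix from 1 to 8, and this number was matched to the replicate number in the sample titles and library names. The match rests on the number alone, but all 8 libraries belong to the same group, so no mean, SD or range depends on it. Of the 10425 Drosophila cells, 10232 have no suffix and 193 share 1 suffix, so they were treated as 1 pooled set with no replicates. The Drosophila libraries were not analysed here as separate samples.

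For each library the share of cells with each label was computed, and means and SDs weight the 8 libraries equally. Shares of single libraries and of the Drosophila set have exact (Clopper-Pearson) 95% binomial intervals. The limit that a count of 0 allows is 3 cells of the total. Intervals and limits cover counting error only. Whether libraries differed in composition was tested with the chi-square statistic of the label by library table, against 100000 random tables with the same margins. The smallest p this can give is 1e-05. That test deals cells to libraries at random and compares these 8 libraries, not conditions. It was also run per label, with Benjamini-Hochberg adjustment over the 10 labels. It was tested on simulated data first, with 40 tables of equal composition and 40 with a changed label. No p-value was computed between species, because 1 pooled set has no spread of its own and an exact permutation of 1 value against 8 cannot give a p below 0.111.

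The questions, the tests, the rule for naming items (all labels where there are 20 or fewer) and a first list of alternatives were fixed before the data were examined. The 5 classes of labels, the ratio of NBs I to GMC, the distances between compositions and the correlations over libraries were added afterwards. Correlations over the 8 libraries have exact two-sided permutation p-values over all pairings. Alternatives covered the weighting of libraries, the labels in the denominator, small libraries, repeated barcodes and the leaving out of each library. A planned cross-table of original against transferred labels and a planned summary of transfer confidence could not be made, since the table gives 1 label and no score per cell. The planned marker genes were not used here for the same reason. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.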

Results

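The deposited annotation covered 31573 cells, of which 21148 were from Tribolium castaneum and 10425 from Drosophila. The Tribolium cells came from 8 libraries of sorted embryonic cells. The libraries held a median of 1913 cells, with a range from 77 cells in library 3 to 7639 cells in library 8. Library 4 held 392 cells, and libraries 3 and 4 together gave 2.22% of the Tribolium cells, whereas library 8 gave 36.1%. A label with no cell in library 3 could still have had a share of up to 3.90%, against 0.0393% in library 8. All 10 labels occurred in both species.

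The first question was which labels the annotated beetle cells carried after the sort for the neuroblast reporter. GMC, the usual abbreviation of ganglion mother cell, the progeny of a neuroblast that divides into neurons or glia, was the most frequent label at 42.2% ± 4.03 of cells (SD, n = 8 libraries). NBs I followed at 20.1% ± 3.91. This label carries the name of type I neuroblasts, which bud off ganglion mother cells directly. GMC exceeded NBs I in 8 of 8 libraries, by 22.0 ± 2.41 percentage points (SD, n = 8). There were 0.475 ± 0.0612 NBs I cells per GMC cell (SD, n = 8).

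The remaining neuroblast labels were minor. Midline_NBs made up 2.27% ± 0.843 of cells, and NBs II/INPs 2.22% ± 2.15 (SD, n = 8). Type II neuroblasts divide through intermediate neural progenitors (INPs) and so give larger lineages. Sensory NBs made up 1.05% ± 1.48 (SD, n = 8), a mean that depended on library 8 and was 0.539% ± 0.333 without it (SD, n = 7). With all cells pooled, which gives library 8 more weight, Sensory NBs made up 2.08% and NBs II/INPs 3.67%. The 4 neuroblast labels summed to 25.7% ± 5.09 of cells (SD, n = 8). The authors had put a question mark behind 2 labels that join type II lineages with newborn neurons. NBs II/INPs/newborn neurons_1? made up 12.7% ± 3.70 and NBs II/INPs/newborn neurons_2? 4.91% ± 2.04 of cells (SD, n = 8).

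Cells with labels outside the nervous system were present in each sorted library. Mesodermal/muscle progenitors made up 9.87% ± 3.10 of cells, and the label plasmatocytes/embryonic hemocytes/macrophages, which names blood cells, 4.66% ± 2.04 (SD, n = 8). Their sum was 14.5% ± 4.49 and ranged from 7.40% in library 4 to 18.9% of cells. The label PCGs, whose meaning is not given in the sources used here, was carried by 2 Tribolium cells in all. All shares are of the annotated cells in the table. Whether it holds every sorted cell is not stated, so they give neither the yield of the sort nor the makeup of the embryo.

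**Figure D1:**
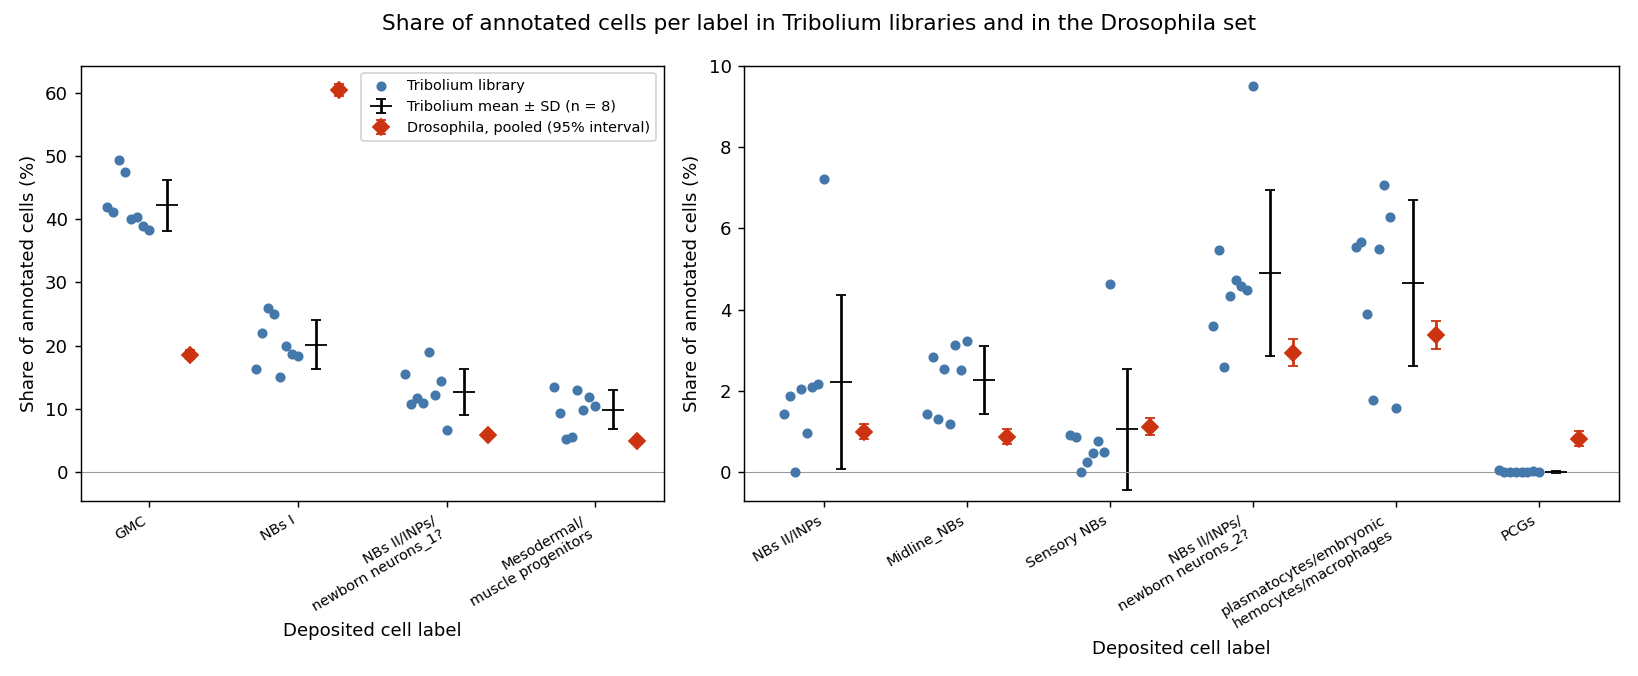
Share of annotated cells (%, y axis) for each deposited label (x axis). Blue points are the 8 Tribolium libraries in numerical order, black bars their mean ± SD, and red diamonds the pooled Drosophila set with its exact 95% binomial interval. NBs I reached 60.5% in Drosophila and at most 26.0% in a Tribolium library, and GMC lay at 18.6% in Drosophila and at 38.3% or more in each Tribolium library.

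The second question was how far the 8 libraries of the same group agreed in composition. Library 8 stood apart in several lineage labels. NBs II/INPs made up 7.21% of its cells (exact 95% interval 6.64% to 7.82%), against 1.51% ± 0.794 in the other libraries (SD, n = 7), a 4.77-fold difference. Sensory NBs made up 4.63% (4.17% to 5.13%) against 0.539% ± 0.333 (SD, n = 7), 8.59-fold. NBs II/INPs/newborn neurons_2? made up 9.50% (8.86% to 10.2%) against 4.25% ± 0.918 (SD, n = 7), 2.23-fold. NBs II/INPs/newborn neurons_1? was lower in library 8 than in each other library, at 6.65% against 13.5% ± 3.01 (SD, n = 7). The blood cell label was also lowest there, at 1.58% against 5.10% ± 1.75 (SD, n = 7), although library 4 lay close to it at 1.79%.

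NBs I and GMC differed less in library 8. NBs I made up 18.3% of its cells, within the range of the other libraries, from 15.1% to 26.0%. GMC made up 38.3%, just under the lowest of the other libraries at 39.0%. Among the other 7 libraries, the labels that varied most against counting error were NBs II/INPs/newborn neurons_1?, with 15.6 times the chi-square expected per degree of freedom, NBs I with 11.1 times and Mesodermal/muscle progenitors with 7.43 times. NBs II/INPs/newborn neurons_1? ranged there from 10.8% in library 2 to 19.1% in library 5, and Mesodermal/muscle progenitors from 5.19% in library 3 to 13.4% in library 1.

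The composition of the 8 libraries differed by more than cell counting error (chi-square 1775 on 63 degrees of freedom, Cramér's V 0.109, resampling permutation p = 1e-05, the smallest it can give). Without library 8 the statistic fell to 279.5 on 54 degrees of freedom, with Cramér's V 0.0587 and the same permutation p of 1e-05. Per label, 9 of 10 labels differed between the 8 libraries after Benjamini-Hochberg adjustment, and 7 of 10 did without library 8. Sensory NBs and NBs II/INPs/newborn neurons_2? no longer passed without it (adjusted resampling permutation p = 0.26 and 0.25). PCGs passed in neither set.

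**Figure D2:**
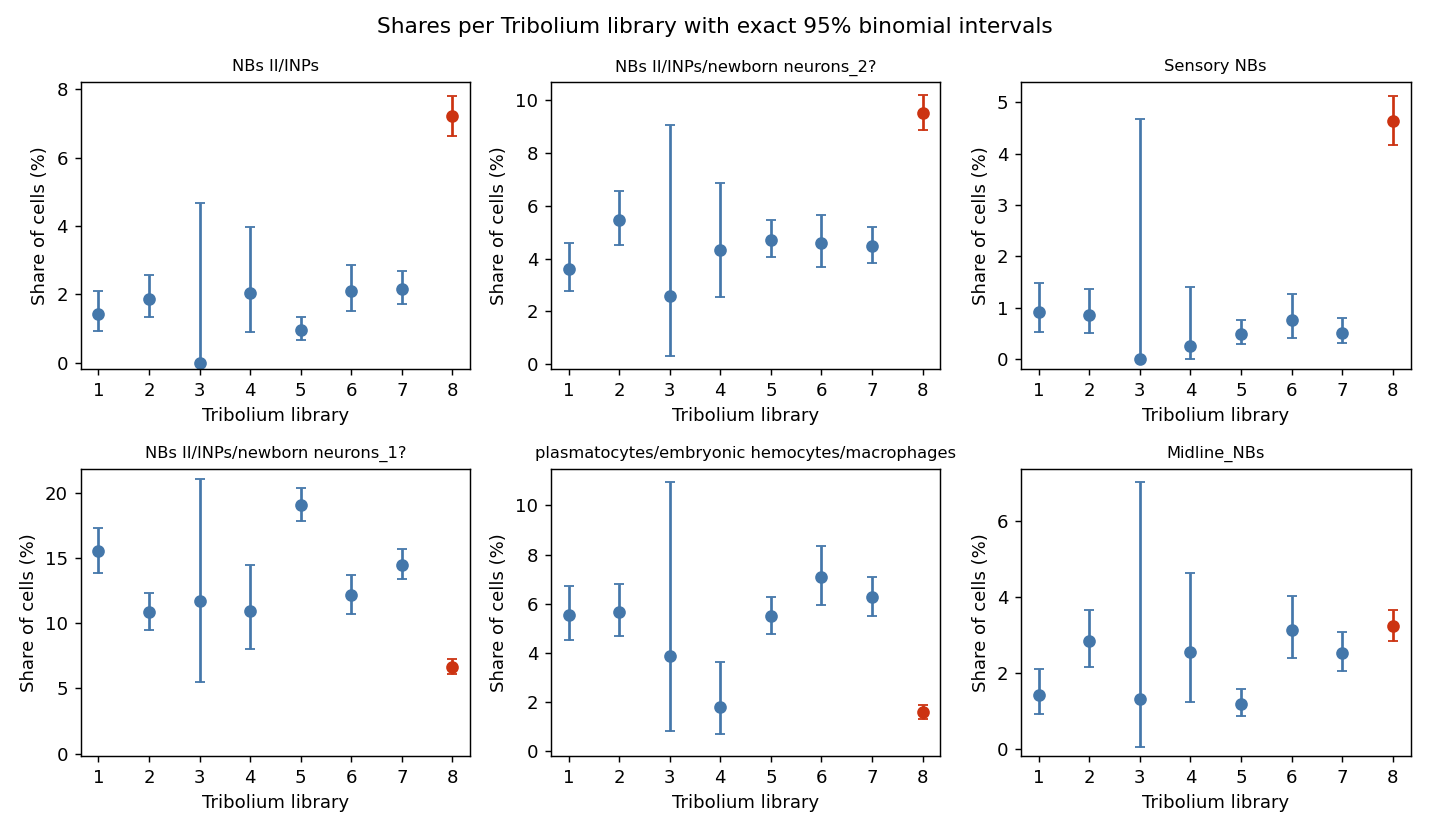
Share of cells (%, y axis) with 6 labels in each Tribolium library (x axis, libraries 1 to 8), with exact 95% binomial intervals and library 8 in red. Library 8 lies above the other libraries in NBs II/INPs (7.21%), NBs II/INPs/newborn neurons_2? (9.50%) and Sensory NBs (4.63%) and below them in NBs II/INPs/newborn neurons_1? (6.65%), and library 3, with 77 cells, has the widest intervals.

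The third question, the one named in the title of the series, was how fly and beetle compare under a shared set of cell labels. NBs I was the most frequent label in Drosophila, at 60.5% of cells (95% interval 59.5% to 61.4%), 3.00 times the Tribolium mean of 20.1%. GMC made up 18.6% in Drosophila (95% interval 17.8% to 19.3%), against 42.2% in Tribolium. The order of the 2 most frequent labels was thus opposite: Drosophila had 3.26 NBs I cells per GMC cell (95% interval 3.10 to 3.43), and the Tribolium libraries had from 0.376 to 0.534. The Drosophila ratio was 6.85 times the Tribolium mean.

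Most other labels made up a larger share of the beetle cells. Shares add up to the whole, so the higher NBs I share in Drosophila lowers its other labels together. Species shares among the cells outside NBs I were not computed. The differences below are therefore not shown to be separate from that of NBs I. Mesodermal/muscle progenitors made up 4.98% of Drosophila cells (95% interval 4.57% to 5.41%), below each of the 8 Tribolium libraries, but the margin to library 3 at 5.19% and library 4 at 5.61% was within counting error. NBs II/INPs/newborn neurons_1? lay at 5.92% (95% interval 5.47% to 6.39%) and Midline_NBs at 0.863% (95% interval 0.695% to 1.06%), again below each Tribolium library. For these labels the intervals overlapped those of the nearest large library, library 8 at 6.65% (6.10% to 7.23%) and library 5 at 1.18% (0.859% to 1.58%). The Tribolium means of mesodermal, newborn neurons_1? and midline cells were 1.98, 2.14 and 2.63 times the Drosophila shares. The 2 labels with a question mark together made up 8.84% of Drosophila cells, against 17.6% ± 3.00 in Tribolium (SD, n = 8). The 3 labels that contain NBs II/INPs summed to 9.83% in Drosophila (95% interval 9.27% to 10.4%) and to 19.8% ± 3.37 in Tribolium (SD, n = 8). The lowest sum was 14.3% in library 3, which held 77 cells. No interval was computed for it, so counting error may cover that margin.

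For 4 labels the Drosophila share lay within the range of the Tribolium libraries. These were NBs II/INPs at 0.988%, NBs II/INPs/newborn neurons_2? at 2.93%, the blood cell label at 3.37% and Sensory NBs at 1.10%. Few cells set the low end of some of these ranges. For NBs II/INPs/newborn neurons_2? only library 3 lay below the Drosophila share, with 2 of 77 cells (2.60%, 95% interval 0.316% to 9.07%), and the other 7 libraries lay at 3.59% or more. For NBs II/INPs, library 3 had 0 of 77 cells and library 5 lay at 0.966% (95% interval 0.678% to 1.34%), within counting error of the Drosophila share. Sensory NBs were above the Drosophila share in library 8 and below it in the other 7 libraries, and with all Tribolium cells pooled their share was the higher, at 2.08%. PCGs went the other way from most labels: 85 Drosophila cells carried this label (0.815%, 95% interval 0.652% to 1.01%) and 2 Tribolium cells did, a ratio of pooled shares of 86.2 (exact 95% counting interval 23.1 to 723.4).

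The Drosophila share was thus outside the range of the 8 libraries for 6 of 10 labels, above it for 2 and below it for 4. If the Drosophila set were exchangeable with the libraries, a label would fall outside with a probability of 22.2%, and labels that add up to the whole are not independent. The high NBs I share in Drosophila by itself lowers the other labels, so the 4 below the range may follow from it. Summed over labels, the Drosophila set differed from single Tribolium libraries by 37.7 to 46.9 percentage points, with a median of 42.5. This is the share of cells that would need another label. NBs I alone lay 40.3 percentage points above its Tribolium mean, so this distance is largely the NBs I difference again. Pairs of Tribolium libraries differed by 3.69 to 26.0 percentage points. No p-value was computed for the species difference, since the Drosophila cells form 1 pooled set with no spread of its own. The table's name places its cells among brain neuroblasts, but the stage of the Drosophila cells and how they were isolated are not given in the sources used here, so the species cannot be separated from these.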

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

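All tests in this part were chosen after the results were seen. The gap of the highest or lowest library to its neighbour was set against the range of the 8 libraries for 15 measures, and 4 passed the 95% critical value of 0.526. Chance flags about 1 in 20 sets when values are normal and equally precise. These libraries differ in size and some measures are sums of others, so the 4 cannot be set against that rate. Of the 4, 3 were in library 8: NBs II/INPs at 7.21% of cells, NBs II/INPs/newborn neurons_2? at 9.50% and Sensory NBs at 4.63%. The last was PCGs in library 1 at 0.057%, which is 1 cell.

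Library 8 was also the largest library, with 7639 cells. Over 8 libraries the shares of NBs II/INPs, Sensory NBs and NBs II/INPs/newborn neurons_2? had a correlation with the number of cells of r = 0.85, 0.87 and 0.89 (exact permutation p = 0.031, 0.020 and 0.012), which did not pass the adjustment over 9 labels (adjusted 0.069 for each). Without libraries 3 and 8, the farthest from the median size, r was -0.36, 0.03 and 0.19, so the values rest on those libraries. A share that rises in proportion to the number of cells would put these 3 labels together at 10.4% in library 7, where the upper 95% bound was 8.02%, so a proportional effect of size is argued against. An effect that sets in only above the size of library 7 stays open. Fewer cells of the newborn neurons_1? and blood cell labels would raise all other labels alike. Among the cells outside those labels, the 3 labels still made up 23.3% in library 8 and at most 9.83% elsewhere, which argues against this too. A candidate explanation for part of the pattern is a shift of cells between the 3 labels that contain NBs II/INPs. Their sum in library 8 was 23.4%, inside the range of the other libraries from 14.3% to 24.7%. It was near the upper end of that range and above the mean of 19.8% ± 3.37 (SD, n = 8). This sum does not cover Sensory NBs, and no biological explanation was tested, since the labels give the same age and treatment for all 8 libraries.

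The species difference in NBs I and GMC was examined in the same way. A line between the 2 labels that lies elsewhere in each species may contribute. Such a shift alone would leave the sum of both labels as it was. The sum was 79.0% in Drosophila, above each Tribolium library (55.1% to 75.3%, mean 62.3% ± 7.56, SD, n = 8). The highest was library 3, with 77 cells, and its 95% interval (64.2% to 84.4%) includes the Drosophila value. These values argue against such a shift as the whole difference, but not against a part in it. That part stays open without expression values or transfer scores. Stage, the sort of the Drosophila cells and the species itself stay open as well and cannot be told apart here.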

How the results depend on the processing

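The choices to leave out labels with a question mark, non-neural labels, libraries or Drosophila cells with a suffix, and to pool cells for the species differences, were made after the data were seen. The test between libraries kept its resampling permutation p of 1e-05 under each of the 3 other settings and without each library in turn, while the chi-square per degree of freedom, 28.2 over all 8 libraries, ranged from 5.18 without library 8 to 37.7 without the libraries of fewer than 500 cells. Counting each barcode once had no effect, as no barcode occurs more than once within a library, and the median of 1913 cells was 1852 or 1974 without each library in turn. Of 44 label shares recomputed with another weighting or denominator, or without small libraries, 41 moved by less than 1 SD. Some of the 44 come from leaving out labels of fewer than 20 cells, which removed only 2 Tribolium cells and so tested nothing. For some labels that SD is wide because of library 8. With all cells pooled, Sensory NBs went from 1.05% to 2.08% and NBs II/INPs from 2.22% to 3.67%. Leaving out the labels with a question mark raised NBs I to 24.3% and GMC to 51.2%, and leaving out the non-neural labels and PCGs raised GMC to 49.3%, by construction, since fewer cells were counted. Of 35 species differences recomputed with cells removed or reweighted, 31 moved by less than 1 SD. With all cells pooled, Drosophila minus Tribolium turned from 0.0518 to -0.973 percentage points for Sensory NBs and went from -1.24 to -2.69 for NBs II/INPs and from -1.99 to -3.43 for NBs II/INPs/newborn neurons_2?. GMC in Drosophila minus Tribolium changed from -23.6 to -30.8 percentage points without the question-mark labels and to -28.9 without the non-neural ones. PCGs changed from 0.805 to 0.882 without the question-mark labels and to 0.781 without the Drosophila cells that carry a suffix. Leaving out 1 of 8 libraries cannot move a mean share by 1 SD, so that measure tests nothing here and values are given instead. Sensory NBs fell to 0.539% without library 8, which gave a species difference of 0.564 percentage points, and without library 3 it was 1.20%, which gave -0.0984. The difference was also below 0 without library 4 (-0.0619), 5 (-0.0294) or 7 (-0.0257), the question-mark labels (-0.0592) or the non-neural ones (-0.0124). Without library 8 the species difference in NBs II/INPs shrank from -1.24 to -0.524. PCGs in Tribolium fell from 0.0105% to 0.00383% without library 1. The planned exclusion of unassigned labels had no cells to remove. The planned restriction to labels present in both species removed none and so tested nothing. The label transfer and confidence alternatives were not run, as the table holds 1 label and no score per cell. The number of cells limited library 3, where 0 of 77 cells carried NBs II/INPs or Sensory NBs, which allows up to 3.90%.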

Other observations

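All tests in this part were chosen after the data were seen. Across the 8 Tribolium libraries, the share of NBs I was lower where the share of Mesodermal/muscle progenitors was higher. Libraries 1 and 5 had mesodermal shares of 13.4% and 13.0% and NBs I shares of 16.3% and 15.1%. Libraries 3 and 4 had mesodermal shares of 5.19% and 5.61% and NBs I shares of 26.0% and 25.0%. Over 8 libraries Pearson's r was -0.97 (exact permutation p = 0.00022, adjusted 0.0080 over 36 pairs of labels) and Spearman's rho -0.95 (exact permutation p = 0.0011, adjusted 0.041). It was the only pair of the 36 to pass the adjustment, and 9 pairs had an unadjusted Pearson p under 0.05. Without libraries 3 and 4, the farthest from the median, r was -0.91 (n = 6, exact permutation p = 0.014), and without library 8 it was -0.98 (n = 7, exact permutation p = 0.00060).

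Shares that add up to the whole tend to move against each other, but the NBs I share among the cells outside the mesodermal label still fell with the mesodermal share (r = -0.96, exact permutation p = 0.00035, n = 8). The 2 libraries with few cells are libraries 3 and 4, so the r of -0.91 without them, given above, is the same check. They did not set the relation. Non-neural cells in the sort would dilute NBs I and GMC alike, yet the number of NBs I cells per GMC cell also fell with the mesodermal share (r = -0.82, rho = -0.86, exact permutation p = 0.022 and 0.011, n = 8; r = -0.93 without libraries 3 and 4, exact permutation p = 0.0056). These values argue against each of the 3 as the whole cause. A hypothesis that stays open is that libraries differed in embryo age within the 35 to 50 hours of collection. If both shares rose with age, NBs II/INPs/newborn neurons_1? would rise with the mesodermal share, but no value here shows how either changes with age. Between them r was 0.53 over 8 libraries (exact permutation p = 0.18) and 0.78 without library 8 (n = 7, exact permutation p = 0.039). It was 0.75 in the 6 larger libraries (exact permutation p = 0.083) and 0.82 without libraries 5 and 8, the farthest from the median of this label (n = 6, exact permutation p = 0.065). The other label that names newborn neurons, NBs II/INPs/newborn neurons_2?, had r = 0.22 over 8 libraries (exact permutation p = 0.61). Its r was 0.35 without library 8 and -0.44 in the 6 larger libraries (exact permutation p = 0.46 for each). The first label rose with the mesodermal share, but that call rests on leaving out library 8, and the second did not follow it throughout. Without an age per library, embryo age cannot be told apart from differences in sorting or labelling.

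The GMC share was lower in libraries with more cells (Spearman's rho = -0.98, exact permutation p = 0.00040, adjusted 0.0036 over 9 labels; Pearson's r = -0.78, exact permutation p = 0.023, adjusted 0.069; r = -0.85 without libraries 3 and 8, exact permutation p = 0.0069). Pairs of Tribolium cells in different libraries shared the same 16 bases 72 times, and 20.8% of the pairs had the same label (exact 95% interval 12.2% to 32.0%), against 22.7% for unrelated cells of the same libraries. Libraries 5 and 7 shared 14 barcodes where their sizes gave 5.72. Taken alone this pair had a one-sided resampling p of 0.0012. Over all 28 library pairs, the resampling p was 0.057 for any departure from the sizes and 0.24 for an equally large standardised excess in at least 1 pair. Among Drosophila cells, 64 pairs shared their 16 bases, and each pair joined a cell with the suffix to 1 without. Thus 64 of the 193 cells with the suffix shared a barcode with a cell without it. How many the set sizes would give was not computed. Of these pairs, 35.9% had the same label (exact 95% interval 24.3% to 48.9%), against 40.9% for unrelated cells. That baseline was drawn from the whole Drosophila set and not from the cells with and without a suffix separately. The Drosophila cells with a suffix carried NBs I in 53.9% of 193 cells (exact 95% interval 46.6% to 61.1%) and those without in 60.6% of 10232 cells.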
